A study of Mus musculus with 8 samples.

How the data were processed

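MicroRNA (miRNA) levels were measured in cultured microvascular smooth muscle cells from male C57BL6 mice that lack Rap1a, a small GTPase of the Ras family. Per the labels, 4 cultures carried an empty shuttle vector (called vector here) and 4 carried the RapCA construct (called RapCA), and the 4 of each group are described as biological replicates. Per the labels' protocols, cells grew in medium with 10% serum and were exposed to virus overnight without serum. They then recovered for 48 h in 0.5% serum before total RNA was taken with a mirVana kit. RNA was labelled with Cy3 and hybridised to a mouse miRNA array, 1 sample per array, so that 1 colour was read. Where the cultures of a group came from is not given in the sources used here beyond the words biological replicate, and p-values measure the spread between these 8 cultures.

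Per the file headers, the authors extracted spot intensity values with Agilent Feature Extraction 10.7.3.1, and the submitters' processing notes name version 10.7. The deposited processed intensity had local background subtracted and was spatially detrended per spot, per the file headers, and it had not been scaled between arrays. A second deposited set of values, the series-wide value table, held exactly the processed intensity of each array. The authors' deposited table of 54 selected miRNAs held whole-number intensity values from 6 to 2316 whose normalization method is not stated. Identical values recur across its columns. Other columns of the deposited scanner output were flags for spots well above background, saturated spots and outlier spots.

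Each array carried 13000 spots that were not controls, from 1857 probes for 650 miRNAs (611 of mouse and 39 of viruses). Control spots and spots with a non-uniformity or population outlier flag were left out, which removed between 2.98% and 4.66% of spots per array. No spot was saturated on any array (0 spots). A probe counted as detected on an array where over 0.5 of its kept spots were well above background. The processed signal was scaled so that the 75th percentile over the 189 probes detected on all 8 arrays was equal. A floor was then set at a scaled signal of 9.61, the median over arrays of percentile 1 among spots well above background, and log2 was taken, so the floor lies at 3.26. Spots were averaged per probe, and probes detected on all arrays of at least 1 group were averaged per miRNA, which left 168 miRNAs for testing. Among the called miRNAs with more than 1 probe, 95 in number, all probes pointed the same way for 95. Values at the floor have no order, and fold changes of miRNAs near it are understated. Their spread is understated too, so for them the p-values do not measure the spread between cultures. For a miRNA not well above background on any array of a group, the fold is given as a bound. It compares the brighter group's mean with the mean, per array of the dimmer group, of the lowest detected probe or the miRNA's own value, whichever was higher.

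Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the 168 miRNAs, threshold 0.05), with no covariate. miRNA lists were fixed before the data were examined: 16 groups of related miRNAs and 7 marker lists, of which 13 had at least 3 tested members. These were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Measures of a single value per array were compared with two-sided exact permutation tests over 70 assignments, for which the smallest possible p is 0.0286. The named miRNAs were set by a rule fixed before the data were examined. It takes the 12 called miRNAs with the largest rise and the 12 with the largest fall, the 4 brightest tested members of each group list and the 2 brightest of each marker list. It also takes the first 20 miRNAs of the authors' deposited table. Those detected on every array of one group and none of the other are taken where a bound on the fold could be given. A few names outside the rule were chosen after their values were seen and are marked as such.

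The method was tested on simulated arrays with the measured probe levels and brightness. For RapCA against vector, 100% of 20 miRNAs changed by 1 on the log2 scale and 100% of 20 changed by 2 were recovered among 185 tested. Their median estimates were 0.999 and 1.96, and 6 of 145 unchanged miRNAs were called. On simulated arrays of equal brightness both sets of 20 were again recovered in full, and 5 of 136 unchanged miRNAs were called. In both runs false calls made up a larger share of all calls than the Benjamini-Hochberg threshold allows. With no miRNA changed, 0 of 186 were called with the measured brightness and 0 of 177 with equal brightness. The changed miRNAs were drawn from the brighter ones, with as many raised as lowered. Recovery of dim miRNAs, and the scaling under an unbalanced shift, were therefore not tested by the simulation. All 8 arrays lay on 1 slide and were scanned in 1 session. The vector arrays filled slide row 1 and the RapCA arrays slide row 2, so slide row and group cannot be told apart. Arrays carry no read depth, and the number of arrays limits the precision.

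Alternatives tried before the data were examined covered the scaling, the filter on dim probes, the summary per miRNA, the floor, outlier spots, the replicate number as a block, array weights, the variance model and leaving out each array in turn. Normexp background correction was planned on mean signals and was run on median signals instead, because the scanner output used here holds median signals. Added after seeing the data were normexp on median signals with and without an offset of 50, scaling by spike-in RNAs, cyclic loess, array brightness as a covariate, and a fit with 1 RapCA array. Gene names were set against a RefSeq gene table of mouse assembly GRCm38, while the array design was annotated on mm9, so no coordinates are given. Of the 168 tested names, 160 had a gene in that table. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.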

Results

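MicroRNA profiles were recorded on 8 single-colour arrays, 4 of Rap1a-deficient mouse microvascular smooth muscle cells with empty vector and 4 of the same kind of cells with the RapCA construct. The series title describes the comparison as knockout against rescue, so the question was which miRNAs differ when RapCA is supplied to cells that lack Rap1a. The construct is not described further in the sources used here, and Rap1a itself is not measured by a miRNA array. Of the 650 miRNAs on the array, 215 were detected on at least 1 array and 168 were tested.

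Before any scaling, miRNA signal was lower on the RapCA arrays. Total gene signal was 69834 ± 9956 (SD, n = 4) on the vector arrays and 35150 ± 14362 (SD, n = 4) on the RapCA arrays, a ratio of 0.503 (exact permutation p = 0.0286, the smallest possible, and 0.16 after adjustment over 7 array measures). RapCA replicate 1 stood apart with 56618, against 26374 to 29218 on the other 3 RapCA arrays. The 4 spike-in RNAs read the same in both groups, with geometric means of 1243 ± 108 and 1243 ± 106 (SD, n = 4 each; exact permutation p = 1). Detected miRNAs numbered 180.25 ± 13.7 on the vector arrays and 143.75 ± 27.1 on the RapCA arrays, a difference of -36.5 that did not pass (SD, n = 4 each; exact permutation p = 0.114, adjusted 0.16). miR-720 gave the most signal on 7 arrays and miR-21 on RapCA replicate 1, with 13.1% to 27.1% of the total.

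**Figure D1:**
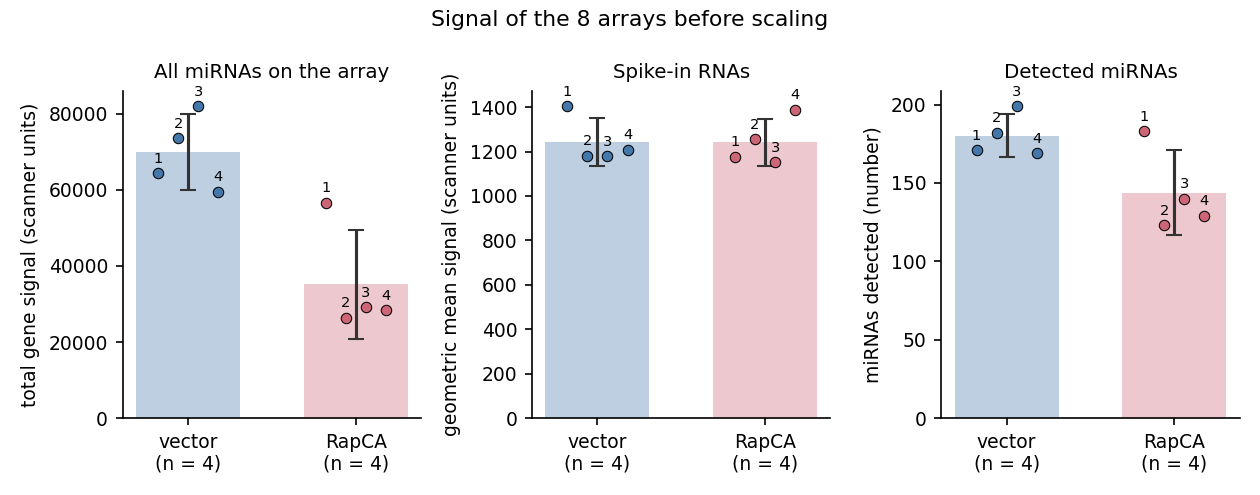
Total gene signal, geometric mean signal of 4 spike-in RNAs (both in scanner units) and number of detected miRNAs on each of the 8 arrays before scaling. Bars show group means with SD (n = 4), points show arrays labelled by replicate number; 3 RapCA arrays lie between 26374 and 29218 in total signal, while the spike-in means of the groups have a ratio of 0.9996.

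After scaling, 44 of the 168 miRNAs were raised and 84 lowered in RapCA cells against vector cells, and 40 were not called. Members of the miR-17/miR-92a family of clusters, which rise with proliferation, were mostly raised, and nearly all tested miRNAs of the imprinted Dlk1-Dio3 cluster were lowered. miR-155, an inflammatory miRNA, was raised, while miR-143, a miRNA of contractile smooth muscle, and the miR-199 and miR-214 cluster of mesenchymal cells were lowered. miR-21, the abundant injury-responsive miRNA, was at 11.6 ± 0.35 in vector and 11.6 ± 0.21 in RapCA cells (log2 signal, SD, n = 4 each), a log2 difference of -0.03 ± 0.18 (SE) that limma did not call (adjusted p = 0.863). Over 28 alternatives miR-21 ranged from -1.10 (without scaling, the 1 setting that called it lowered) to 0.41. The groups did not overlap for 114 of the 168 tested miRNAs. Chance gives such separation for 2.86% of miRNAs picked without regard to group. Only 115 miRNAs had a probe detected on all 8 arrays, and for the others the detection filter itself favours separation. The miRNAs share the same 8 arrays and are not independent.

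The split into raised and lowered depended on the scaling, because the median log2 change of all tested miRNAs was -0.30 under the main scaling. It was -0.61 with the percentile over all probes (28 raised, 103 lowered), -1.03 without scaling (10 raised, 113 lowered) and -1.08 with spike-in scaling (9 raised, 111 lowered). It was -0.22 with quantile normalization (50 raised, 77 lowered) and -0.03 with cyclic loess (53 raised, 53 lowered). Normexp correction gave 80 raised and 20 lowered with an offset of 50 and 49 raised and 58 lowered without one. Spike-in scaling, cyclic loess and normexp on median signals were added after the data had been seen. A fold change of 0 means no change relative to the 75th percentile of the 189 probes detected on all 8 arrays, so the median miRNA lies below 0.

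Among the raised miRNAs, miR-714 went from 3.49 ± 0.10 to 6.89 ± 0.53 (log2 signal, SD, n = 4 each), a log2 fold change of 3.39 ± 0.22 (SE; limma adjusted p = 1.08e-06). miR-1224 rose by 2.26 ± 0.23 and miR-188-5p by 2.13 ± 0.15 (log2 fold change ± SE, n = 4 per group). miR-135a* rose by 2.08 ± 0.15, miR-689 by 2.07 ± 0.19, miR-7a by 2.06 ± 0.08 and miR-709 by 1.90 ± 0.23. miR-7a, miR-135a* and miR-1895, the last raised by 1.75 ± 0.17, were well above background on 2 of the 4 vector arrays and on all 4 RapCA arrays. The floor limits these 3 values, so raised miRNAs are not ranked: miR-7a had 2.74 and miR-1895 2.26 with a floor at 1, and miR-135a* 2.86 with total gene signal. miR-685 rose by 1.72 ± 0.14. miR-155 rose by 1.52 ± 0.12 (limma adjusted p = 2.82e-06), but its value without scaling was 0.45 and no longer passed. Without scaling, miR-714, miR-1224, miR-135a*, miR-7a, miR-188-5p, miR-689, miR-709, miR-1895, miR-92a and miR-685 were the 10 miRNAs that remained raised, miR-714 by 2.42. The names miR-714, miR-689 and miR-685 have no gene in the mouse table used here, and what their probes bind was not tested.

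Among lowered miRNAs with signal on every array, miR-127 went from 7.26 ± 0.26 to 5.46 ± 0.18 (log2 signal, SD, n = 4 each), a log2 fold change of -1.80 ± 0.14 (SE; limma adjusted p = 3.20e-06). miR-143 changed by -1.62 ± 0.15, miR-379 by -1.55 ± 0.09, miR-199a-5p by -1.45 ± 0.10, miR-103 by -1.42 ± 0.09 and miR-152 by -1.28 ± 0.13. miR-431 (-1.86 ± 0.12) and miR-434-5p (-1.58 ± 0.13) were detected on 1 of 4 RapCA arrays, miR-324-5p (-1.31 ± 0.12) on 2 and miR-410 (-1.34 ± 0.14) on 3. miR-455, miR-541, miR-335-5p and miR-411* were detected on all 4 vector arrays and on no RapCA array. They were at least 1.92-fold, 1.56-fold, 1.20-fold and 1.05-fold lower in RapCA cells, with limma adjusted p-values of 7.46e-07, 1.08e-06, 8.22e-06 and 7.59e-06. The floor cuts their spread on the RapCA arrays (SD 0 for miR-335-5p and miR-411*, 0.04 for miR-541 and 0.05 for miR-455). These p-values therefore do not measure the spread between RapCA cultures. Normexp correction with an offset of 50 turned miR-455, miR-541, miR-335-5p, miR-411*, miR-434-5p, miR-324-5p and miR-410 to values from 0.01 to 0.42. It also ended the calls of miR-431 (-0.06) and miR-152 (-0.17), and left miR-127 at -0.74, miR-103 at -0.60, miR-143 at -0.55, miR-379 at -0.50 and miR-199a-5p at -0.97, all still lowered. The offset is added before scaling, so it lifts dim signals most on the dim RapCA arrays. With it the median log2 change of all tested miRNAs was 0.37. A dim miRNA that turns above 0 therefore cannot be told apart from an effect of the offset, here and below. Without the offset, 0 of the main lowered calls became raised.

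**Figure D2:**
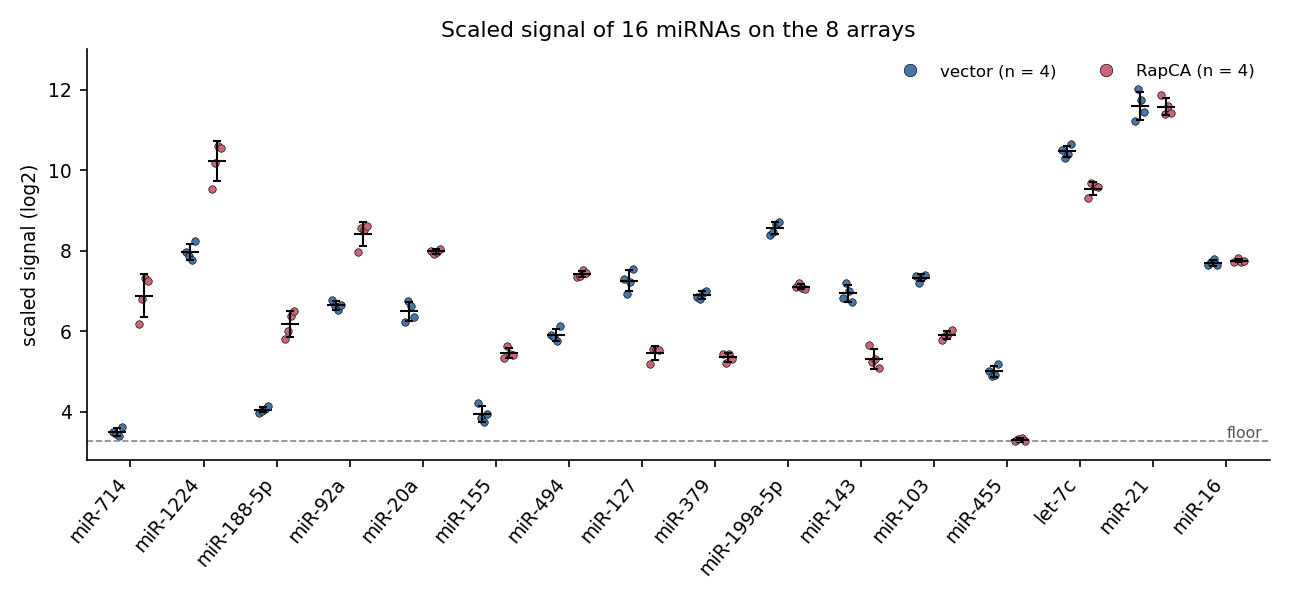
Scaled log2 signal of 16 miRNAs on the vertical axis for 4 vector and 4 RapCA arrays, points for arrays, with the mean and SD in black and the floor at 3.26 as a dashed line. miR-714 sits at a mean of 3.49 in vector and 6.89 in RapCA cells, miR-127 at 7.26 and 5.46, and miR-21 at 11.6 in both; without scaling between arrays miR-714 stays raised (2.42), while miR-21 and miR-16 have log2 changes of -1.10 and -1.01.

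The miR-17/miR-92a cluster and its paralogs are polycistrons that rise in dividing cells. Of their 10 tested members, 8 were raised, 1 was lowered and 1 was not called, with a median log2 fold change of 1.09. miR-19a rose by 1.96 ± 0.28, miR-92a by 1.78 ± 0.14, miR-20a by 1.49 ± 0.12 and miR-19b by 1.25 ± 0.16 (log2 ± SE, n = 4 per group). miR-25 rose by 0.53 ± 0.10. The lowered member was miR-93 (-0.20 ± 0.08) and the uncalled one miR-106b (0.24 ± 0.19), both named after their values were seen. miR-93 was called lowered in 10 of 28 alternatives and in 0 of the 8 that leave out 1 array (nearest to 0 without RapCA replicate 2, -0.06), and miR-106b was called raised in 3 of 28 but had -0.83 with spike-in scaling. Relative to all other miRNAs the list was higher (camera adjusted p = 0.000277), a call lost with an estimated correlation (adjusted p = 0.246). Without scaling, and with spike-in scaling, the list median was 0.02 with 1 member raised and 1 lowered, and with the percentile over all probes 5 were raised.

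Dlk1-Dio3 is an imprinted domain on mouse chromosome 12 whose miRNAs come from the maternal copy. Of its 30 tested miRNAs, 27 were lowered in RapCA cells, with a median log2 fold change of -0.86. It was -0.75 with the 7 members not detected on any RapCA array set to their bounds. The 27 lowered members include miR-127, miR-379 and miR-431, and miR-299* at -0.65 ± 0.12. miR-409-3p, miR-409-5p and miR-369-5p were detected on 1 of 4 RapCA arrays, so their values of -0.89 ± 0.12, -0.94 ± 0.12 and -0.75 ± 0.10 (log2 ± SE, n = 4 per group) rest on signals near the floor. They were -2.99, -2.51 and -3.07 with total gene signal, while normexp with an offset of 50 turned them to 0.44, 0.43 and 0.44 and miR-299* to 0.02. miR-494 was the 1 member that was raised, by 1.51 ± 0.10 (limma adjusted p = 1.08e-06; 0.44 and not called without scaling). miR-136 (-0.76 ± 0.38) and miR-377 (-0.41 ± 0.20) were not called and were named after their values were seen. Each was lowered in 6 alternatives, among them those without vector replicate 1 (-1.01 and -0.55) and without RapCA replicate 1 (-1.02 and -0.54), but miR-136 turned to 0.27 with the brightness covariate and miR-377 to 0.30 under normexp with an offset of 50. The list was lower than all other miRNAs (camera adjusted p = 0.000225), a call lost with an estimated correlation (adjusted p = 0.246) and with the 11 members whose probes were detected on all 8 arrays (median -0.91, adjusted p = 0.0781). The list median was below 0 under every scaling tried, but normexp with an offset of 50 turned it to 0.29 with 2 members lowered and 8 raised (camera adjusted p = 0.907), and normexp without an offset gave -0.40 with 15 lowered.

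In a fit added after the data had been seen, which kept RapCA replicate 1 as the only RapCA array, whose total signal was closest to the vector arrays, limma called 47 raised and 59 lowered of 196 miRNAs. There, 8 miR-17/miR-92a members were raised and 19 Dlk1-Dio3 members lowered. That fit assumes that the lone RapCA array varies like the vector arrays.

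The contractile smooth muscle list had 11 miRNAs on the array, of which 4 were tested. All 4 were lowered, with a median of -0.76 (camera adjusted p = 0.0807, and 0.246 with an estimated correlation). miR-143 changed by -1.62 ± 0.15, miR-10a by -0.78 ± 0.10 and let-7d by -0.66 ± 0.09 (log2 ± SE, n = 4 per group). let-7d is also in the let-7 list and miR-10a in the list of miR-10, miR-99, miR-100 and miR-125, so these lists are not independent. miR-145, the partner of miR-143 in one transcript, fell from 4.02 ± 0.16 to 3.27 ± 0.02 (log2 signal, SD, n = 4 each; limma adjusted p = 6.62e-05) and was not well above background on any RapCA array, so no fold is given. Its RapCA values lie at or near the floor, so that p-value does not measure the spread between RapCA cultures. Normexp with an offset of 50 turned miR-145 to 0.45 and ended the call of miR-10a (-0.30). The list of synthetic, proliferative smooth muscle was mixed, with 3 of 6 raised and 2 lowered (camera adjusted p = 0.564). miR-31 rose by 0.24 ± 0.08 and miR-26a and miR-24 were lowered, with values of -1.25 ± 0.08 and -0.81 ± 0.09, while miR-221 had 0.07 ± 0.09 and was not called (raised in 2 and lowered in 3 of 28 alternatives). Without RapCA replicate 3 miR-31 was not called (0.22). miR-31 and miR-221 turned negative with the percentile over all probes (-0.17 and -0.34), without scaling (-0.83 and -0.996) and with spike-in scaling (-0.83 and -0.995), as did the list median of 0.15 (-0.26, -0.91 and -0.91).

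Of the let-7 family, which restrains growth in many tissues, 8 of 9 members were lowered, with a median of -0.66 (camera adjusted p = 0.0807, and 0.254 with an estimated correlation). let-7c changed by -0.92 ± 0.11, let-7a by -0.73 ± 0.09 and let-7b by -0.58 ± 0.14 (log2 ± SE, n = 4 per group). let-7i had -0.02 ± 0.11 and was not called. It was lowered with the percentile over all probes (-0.43), without scaling (-1.09) and with spike-in scaling (-1.09), and raised with cyclic loess (0.33). All 5 tested miRNAs of the miR-199 and miR-214 cluster were lowered, with a median of -1.24. miR-199b* changed by -1.26 ± 0.12, miR-214 by -1.24 ± 0.15 and miR-199a-3p by -0.90 ± 0.10. All 5 of the miR-23/27/24 clusters were lowered as well, among them miR-23b by -0.97 ± 0.09, miR-27a by -0.55 ± 0.15 and miR-23a by -0.38 ± 0.09, with a median of -0.81. In that list 3 of 5 were lowered without RapCA replicate 2 (miR-27a -0.31 and miR-23a -0.19, not called), with quantile normalization, with cyclic loess and with 1 RapCA array. Both lists had a camera adjusted p of 0.0807, with adjusted p = 0.292 and 0.246 for an estimated correlation. The medians of these 3 lists and of the contractile list were below 0 under every scaling tried.

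The miR-29 family, which targets collagens, had 3 of 4 members raised with a median of 0.72 (camera adjusted p = 0.0807, and 0.246 with an estimated correlation), but the median was -0.18 without scaling and -0.19 with spike-in scaling. miR-29b rose by 1.503 ± 0.35, miR-29a by 0.98 ± 0.11 and miR-29c by 0.47 ± 0.19, and miR-29b*, detected on 1 of 4 RapCA arrays, had 0.14 ± 0.10 (log2 ± SE, n = 4 per group) and -0.29 with spike-in scaling. miR-29c was called in 14 of 28 alternatives and in 3 of the 8 that leave out 1 array, but not without vector replicate 1 (0.34) or 4 (0.43) or RapCA replicate 1 (0.36), 3 (0.496) or 4 (0.51). In the miR-15/16 family, which restrains the cell cycle, miR-15a (0.55 ± 0.16) and miR-322 (0.53 ± 0.13) were raised, and miR-15b (0.09 ± 0.10) and miR-16 (0.06 ± 0.08) were not called, each raised in 2 and lowered in 3 of 28 alternatives. The median of that family was 0.31 (camera adjusted p = 0.150) and turned to -0.10 with the percentile over all probes and to -0.76 without scaling and with spike-in scaling.

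The miR-30 family had 4 of 7 members lowered, with a median of -0.30, the same as that of all tested miRNAs (camera adjusted p = 0.374), that turned to 0.33 under normexp with an offset of 50, with 3 raised. From 0 to 6 members were lowered over 28 alternatives, 1 of them without RapCA replicate 2 (median -0.10, miR-30a -0.23) and with cyclic loess (median -0.007), and 6 with the percentile over all probes, without scaling and with spike-in scaling. miR-30b was also not called without RapCA replicate 4 (-0.24). miR-30c changed by -0.93 ± 0.12, miR-30a by -0.45 ± 0.08 and miR-30b by -0.30 ± 0.09, while miR-30d had -0.30 ± 0.13 and was not called (lowered in 8 of 28 alternatives; log2 ± SE, n = 4 per group). The call of miR-30c was lost under normexp with an offset of 50 (-0.03), as was that of miR-30a, which cyclic loess also ended (-0.09). Of the clusters of miR-10, miR-99, miR-100 and miR-125, 5 of 7 members were lowered and 1 raised (median -0.49, camera adjusted p = 0.574). Over 28 alternatives 0 to 6 were lowered, 3 of them without vector replicate 4, RapCA replicate 2 or RapCA replicate 3 (miR-125a-5p -0.39, -0.38 and -0.51, miR-100 -0.30, -0.20 and -0.35, none called). miR-125a-5p was not called without vector replicate 1 (-0.44) either, nor miR-100 without vector replicate 3 (-0.34). miR-125a-5p changed by -0.49 ± 0.18 and miR-100 by -0.37 ± 0.12, and miR-125b-5p had 0.15 ± 0.13 and was not called (raised in 3 alternatives, 0.26 without RapCA replicate 1, and lowered in 2, without scaling and with spike-in scaling, at -0.92). limma called 0 of the 3 p53-induced miR-34 miRNAs, and 0 at an unadjusted p under 0.05, with -0.23 ± 0.13 for miR-34a, -0.19 ± 0.10 for miR-34c and 0.31 ± 0.25 for miR-34b-5p (-0.76 without scaling; camera adjusted p = 0.889 for the list). Their median of -0.19 was above 0 in 6 of 28 alternatives, the highest being 0.29 under normexp with an offset of 50, which raised 1 member, as did cyclic loess (0.12). It was also above 0 without RapCA replicate 2 (0.07), while miR-34a was lowered without vector replicate 1 (-0.34). With the percentile over all probes, without scaling, with spike-in scaling and with array weights, 2 of the 3 were lowered (medians -0.59, -1.22, -1.22 and -0.28).

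Among the lists with fewer than 3 tested members, the hypoxia-induced miR-210 changed by -0.54 ± 0.11, a call lost with cyclic loess (-0.17) and under normexp with an offset of 50 (0.02). miR-212, which the cAMP response factor CREB induces, had 0.43 ± 0.18 and was not called (limma adjusted p = 0.0546). It was called raised in 11 of 28 alternatives, among them those without vector replicate 1 (0.53) or 4 (0.58) or RapCA replicate 1 (0.52) or 2 (0.61). It ranged from -0.61 without scaling and with spike-in scaling, over 0.006 with the brightness covariate, to 0.66 with array weights. miR-669f and miR-467f of the Sfmbt2 cluster rose by 0.66 ± 0.21 and 1.10 ± 0.27 (log2 ± SE, n = 4 per group), but their median of 0.88 turned to -0.13 without scaling and -0.12 with spike-in scaling, and miR-669f was not called without vector replicate 1 (0.55). miR-467f was detected on 2 of the 4 vector arrays. Adjusted over the list alone, the counts were those given above for every list except 2. The miR-30 family then had 3 lowered, and miR-212 was raised.

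**Figure D3:**
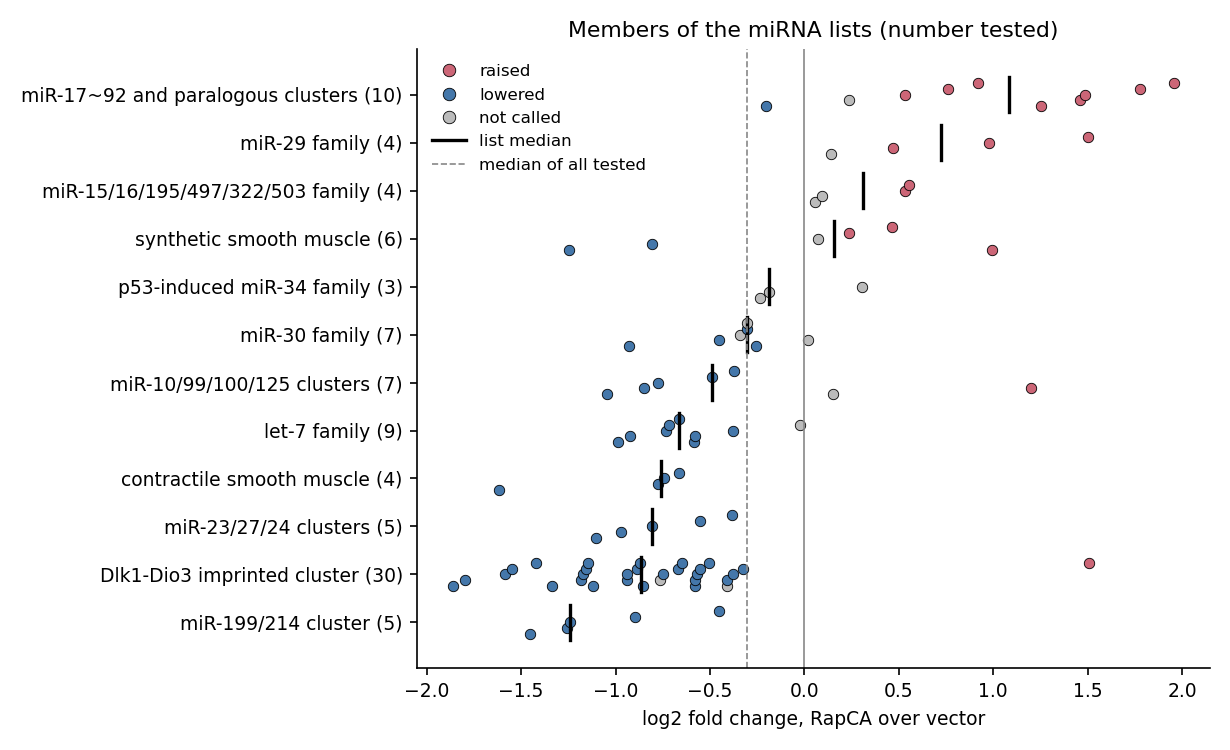
Log2 fold change of RapCA over vector (horizontal axis) for each tested member of the 12 group lists with at least 3 tested members, coloured by limma call, with the list median as a bar and the median of all 168 miRNAs (-0.30) dashed. The miR-17/miR-92a list has its median at 1.09 and the Dlk1-Dio3 list at -0.86 with miR-494 alone at 1.51; without scaling between arrays the first becomes 0.02 and the medians of the miR-29, miR-15/16 and synthetic lists turn negative, as do the miR-15/16 and synthetic medians with the percentile over all probes.

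Marker miRNAs of other cell types were nearly absent. Of 31 markers of endothelial, blood, epithelial, striated muscle, neuronal and liver cells, 29 were not detected on any array, among them all those of endothelial, blood, epithelial and liver cells. miR-206, a striated muscle marker, was the 1 marker that could be tested, with 4.25 ± 0.15 in vector and 4.31 ± 0.05 in RapCA cells (log2 signal, SD, n = 4 each), a change of 0.06 ± 0.10 that limma did not call (adjusted p = 0.579). It was called lowered without scaling (-0.58) and with spike-in scaling (-0.61), and raised with cyclic loess (0.29) and under normexp with an offset of 50 (0.56). Of 39 viral miRNAs, which serve as a background check, 36 were not detected on any array. The 3 tested viral probes were all raised with a median of 0.79 (camera adjusted p = 0.0807, and 0.306 with an estimated correlation), a median of -0.06 without scaling and -0.09 with spike-in scaling. Among them, mcmv-miR-M23-1-5p rose by 0.56 ± 0.21 (called in 16 of 28 alternatives, but not without vector replicate 2, 0.44, or 3, 0.48, or RapCA replicate 3, 0.49, or 4, 0.51) and mghv-miR-M1-2 by 1.13 ± 0.24 (log2 ± SE, n = 4 per group). Raised calls of similar size were therefore not cleared by this background check. Among these are miR-15a, miR-25, miR-29a and miR-322, which turned negative without scaling.

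The authors' deposited table lists 54 miRNAs, 27 with higher and 27 with lower means in RapCA cells. Of these, 49 were tested here, 49 had the same direction, and 48 were called by limma, the exception being miR-136. This list was selected on the same 8 samples and is not independent evidence of direction. In the authors' deposited table the means gave log2 ratios of 3.31 for miR-714 and 2.43 for miR-1224, and of -2.10 for miR-431 and -2.05 for miR-455. Across the 49 miRNAs, which are not independent replicates, these log2 ratios and the limma values had r = 0.976 and a median absolute difference of 0.179. miR-1897-5p of that table was not detected on all arrays of either group and was not tested here.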

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

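The tests of the lower RapCA signal were chosen after the array signals had been seen. In 167 groups of 4 arrays, 17 had 1 array far from the other 3 by Dixon's test, where chance gives about 8.35, and 13 of the 17 concerned RapCA replicate 1. Its total gene signal was 56618 against 26374 to 29218 on the others, and its scaling percentile relative to the mean array was 1.38 against 0.519 to 0.572. On the log2 scale, RapCA replicate 1 lay below the other RapCA arrays for miR-125b-5p (10.15), miR-127 (5.19), miR-214 (6.74), miR-30c (4.81), miR-30d (4.75), miR-31 (6.91), miR-467f (3.48), miR-712 (4.22) and miR-92a (7.98). It lay above them for miR-15a (8.44) and miR-322 (6.99). Elsewhere, vector replicate 1 had a spike-in mean of 1405 against 1180 to 1207 and a miR-30a signal of 7.17, and vector replicate 2 had 3.88 for miR-369-5p and 6.45 for miR-107.

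Most miRNAs were dimmer on the RapCA arrays before scaling, with a total signal ratio of 0.503. Hybridisation or scanning weaker for all spots alike would lower the spike-in RNAs too, but their mean log2 difference was -0.000485. Of 5 other positive controls, whose targets are not stated, hur_4, hur_2, hur_1 and hur_6 were lower on the RapCA arrays by log2 values of -0.70, -0.36, -0.30 and -0.19. The fifth, mr_1, was higher by 0.12, and none passed the threshold (n = 4 per group, exact permutation, lowest adjusted p = 0.257). These means pool unlike arrays. Against the vector mean, RapCA replicates 2 to 4 had -0.89, -0.50, -0.42 and -0.40 for the hur controls in that order and -0.01 for mr_1. RapCA replicate 1 had -0.12, 0.07, 0.06 and 0.44, and 0.50 for mr_1. The hur controls were thus lower mainly on the dim RapCA arrays, so a loss that spares the spike-ins stays open. Less RNA as the only difference would leave no miRNA brighter on the RapCA arrays, and 10 were brighter without scaling, miR-714 by 2.42 and miR-1224 by 1.19. Of these 10, 3 (miR-714, miR-689 and miR-685) have no gene in the mouse table used here, and what their probes bind was not tested. Less RNA or weaker labelling together with changes in single miRNAs, and a lower miRNA content of RapCA cells, stay open, since neither the RNA amount per array nor the step at which spike-ins were added is given in the sources used here. Slide row, which splits the arrays as the groups do, cannot be told apart from the construct.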

How the results depend on the processing

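Of the values of the named miRNAs under all alternatives, 2230 kept their call, 138 fell short of it, 69 newly passed and 62 changed sign. A change of sign was counted where the main fit or the alternative gave a call. It need not pass the threshold in the new direction. The cause was not tested unless stated. The series-wide values, 1 of the 28 alternatives, are the same intensities as in the main choices, so their agreement was fixed in advance. The count of changed miRNAs, 44 raised and 84 lowered with the main choices, ranged over the alternatives from 35 raised and 57 lowered of 115 where probes had to be detected on all 8 arrays to 46 raised and 100 lowered of 188 with total gene signal. Normexp on median signals, spike-in scaling, cyclic loess, the brightness covariate and the fit with 1 RapCA array were added after seeing the data. Raised miRNAs numbered 28 with the percentile over all probes, 10 without scaling, 9 with spike-in scaling and 80 with normexp and its offset. Lowered miRNAs numbered 20 with that offset and 53 with cyclic loess. miR-17/miR-92a members raised, 8 with the main choices, were 5 with the percentile over all probes and 1 without scaling or with spike-in scaling. Dlk1-Dio3 members lowered, 27 with the main choices, were 9 of 11 where probes had to be detected on all 8 arrays (fewer miRNAs tested), 2 with normexp and its offset and 15 with normexp and no offset. Lists past the threshold by camera at the preset correlation, 2 with the main choices, were 1 with probes detected on all 8 arrays (Dlk1-Dio3 dropped out), 5 with probes detected on at least 1, 8 with no detection filter, 5 with normexp and its offset and 7 without the offset. With the main choices, camera with an estimated correlation passed no list (lowest adjusted p = 0.246). The fry test passed every tested list except the miR-34 family (fry adjusted p = 0.486). It asks whether a list's members changed at all, so it does not set a list apart from the other miRNAs. The offset of 50 is added before scaling and so lifts dim arrays most: 14 main lowered calls became raised with it and 0 without it. Leaving out each array in turn gave 110 to 131 changed, 39 to 49 raised, 61 (without RapCA replicate 2) to 85 lowered, 8 to 8 miR-17/miR-92a members raised, 22 to 29 Dlk1-Dio3 members lowered, 2 to 3 lists and a difference in detected miRNAs of -49.6 (without RapCA replicate 1, exact permutation p = 0.0286) to -29.6. Without scaling and with spike-in scaling these values turned negative: mcmv-miR-M23-1-5p -0.51, miR-125b-5p -0.92, miR-15a -0.52, miR-15b -0.97, miR-16 -1.01, miR-221 -0.996 and -0.995, miR-25 -0.54, miR-29a -0.0904 and -0.0899, miR-29c -0.59, miR-31 -0.83, miR-322 -0.54, miR-669f -0.39 and miR-720 -0.53 under both, and mcmv-miR-m88-1 -0.060 and -0.0861, miR-206 -0.58 and -0.61, miR-712 -0.22 and -0.23. miR-212, miR-106b and miR-34b-5p, not called there, were at -0.61, -0.83 and -0.76 under both, and miR-29b* at -0.29 with spike-in scaling. With the percentile over all probes miR-15b became -0.32, miR-16 -0.35, miR-221 -0.34 and miR-31 -0.17. Cyclic loess gave let-7i 0.33, miR-30b 0.13 and miR-93 0.0443. Array brightness as a covariate gave mcmv-miR-M23-1-5p -0.0828 and miR-720 -0.36, and turned miR-136, not called, to 0.27. Normexp without an offset gave miR-93 0.0186. Normexp with its offset gave miR-100 0.0365, miR-145 0.45, miR-148a 0.15, miR-181a 0.33, miR-181b 0.28, miR-210 0.0214, miR-26b 0.0931, miR-299* 0.0237, miR-30b 0.33, miR-324-5p 0.15, miR-335-5p 0.31, miR-369-5p 0.44, miR-409-3p 0.44, miR-409-5p 0.43, miR-410 0.0135, miR-411* 0.42, miR-434-5p 0.16, miR-455 0.16, miR-541 0.28 and miR-93 0.33. With the replicate number as a block, limma called 118 miRNAs, 41 raised and 77 lowered. Same-numbered arrays did not deviate together (correlations of -0.65, -0.60, -0.55 and 0.63 for numbers 1 to 4), and only number 4 matched its own number best, so the numbers were not taken as pairs. Signal over background limits the dim miRNAs: 11 lowered ones were not detected on any RapCA array. A slide block could not be fitted because there was 1 slide, and normexp on mean signals was not run.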

Other observations

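Among lowered miRNAs outside the lists, a few more were picked after their values were seen, and no theme was tested on them. miR-107 changed by -0.93 ± 0.08, miR-148a by -0.94 ± 0.15, miR-181b (detected on 1 of 4 RapCA arrays) by -1.14 ± 0.11, miR-181a by -0.54 ± 0.10 and miR-26b by -0.61 ± 0.14 (log2 ± SE, n = 4 per group, all called by limma). All 5 were below 0 under every scaling tried (miR-181b -1.71 with spike-in scaling), while normexp with an offset of 50 turned miR-148a, miR-181a, miR-181b and miR-26b above 0 and ended the call of miR-107 (-0.15). miR-26b was not called without RapCA replicate 2 (-0.34).

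The test over other splits of the arrays was planned, and the remaining tests below were chosen after the results were seen. Of the 35 splits of the 8 arrays into 4 and 4, the real one was the 1 split with as many calls as the 44 raised and 84 lowered. The highest other split had 0 limma calls at an adjusted p under 0.05 and 31 at an unadjusted p under 0.05, against 133 for the real split. All other splits mix vector and RapCA arrays, which widens the spread within each side and leaves few calls. A share of 1 in 35 is the smallest possible, so chance is unlikely but not excluded.

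The rise of miR-17/miR-92a and the fall of Dlk1-Dio3 miRNAs were weighed against array brightness and other cell types. With brightness as a covariate, the list medians relative to all miRNAs went from 1.39 to 1.55 for miR-17/miR-92a (1.503 to 2.18 leaving out 1 array at a time) and from -0.56 to -0.62 for Dlk1-Dio3 (-0.74 to -0.50). Log2 brightness was 0.20 to 0.78 on the vector arrays and -0.95 to -0.81 on RapCA replicates 2 to 4. Only RapCA replicate 1 (0.46) overlapped, and without it brightness nearly follows the group. The values argue against brightness as the whole cause of either only as far as that 1 array allows. Of 22 marker miRNAs of endothelial, blood, epithelial and liver cells, 0 were detected on a RapCA array. Their highest mean signal there was 3.35 ± 0.12 (SD) for miR-223, a blood marker, which lay at the floor of 3.26 on the vector arrays. This argues against these 4 cell types as the cause only as far as the dimmer RapCA arrays could detect their markers. Other cell types, and a change in the proliferative or differentiation state of the cells with RapCA, stay open and were not tested. An effect of slide row cannot be told apart from the construct.

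Probes whose names have no gene in the mouse table used here were often raised, a set chosen after some of its members were seen to be raised, so no p is given. These are the 3 viral probes and miR-685, miR-689, miR-712, miR-714 and miR-720. Of these 8, 7 were raised, against 37 of the 160 others, with miR-712 at 0.84 ± 0.21, mcmv-miR-m88-1 at 0.79 ± 0.16 and miR-720 at 0.54 ± 0.25 (not called; raised in 6 of 28 alternatives, among them those without vector replicate 4, 0.66, RapCA replicate 1, 0.81, or RapCA replicate 2, 0.61, and lowered in 3), and without scaling 3 of the 8 (miR-714, miR-689 and miR-685) were raised. With array brightness as a covariate, 4 of the 7 were still raised, the median of the 8 above all miRNAs went from 1.29 to 0.73 (0.33 to 0.91 leaving out 1 array at a time), and mcmv-miR-M23-1-5p (-0.08) and miR-720 (-0.36) turned negative. Array brightness therefore stays open for part of the set, and this fit too leans on RapCA replicate 1. What these probes bind was not tested.

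A further hypothesis was that neighbouring miRNA genes change alike. In 12 groups of 49 hairpin genes at most 10 kb apart, the mean absolute deviation within groups was 0.411 against a median of 0.590 in 100000 shuffles (permutation p = 0.00276). Without the groups that hold miR-17/miR-92a or Dlk1-Dio3 members, 8 groups of 19 genes gave 0.376 against 0.515 (permutation p = 0.110). With fewer genes this did not pass, and the relation outside those lists stays open. miR-188-5p, raised by 2.13, lies in such a group with miR-500, miR-362 and miR-532, which had mean values of -0.24, -0.21 and -0.27 per hairpin.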
